A study of Mus musculus and Macaca mulatta with 39 samples.

How the data were processed

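ChIP-seq for H3K27ac and H3K4me2 was carried out on embryonic cortex of mouse and rhesus. Per the labels' protocols, mouse tissue was processed directly and rhesus tissue was thawed and dissected, tissue was crosslinked with formaldehyde and sonicated, and both marks were precipitated from soluble chromatin. The labels list 39 samples. Of these, 26 ChIP samples had a region list and 13 input samples (8 mouse, 5 rhesus) had none among the files used here. Groups were taken from the labels' tissue and age, giving 4 mouse and 3 rhesus tissues for each of the 2 marks. Per the series' design text, replicates of a tissue were biological ones, and the ChIP samples of a replicate shared an input.

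Each deposited file holds region positions only, in 3 columns (chromosome, start, end), so the unit is a called interval in bp with no count, signal or score from the authors. Regions were called separately for each sample. Per the submitters' processing notes Bowtie 0.12.9 was used, and the builds hg19 and mm9 are named without a role. The region caller, its threshold and the rhesus build are not given in the sources used here. Tests on the files showed starts on a 25-bp grid, a minimum width of 500 bp except for regions of 405, 430 and 455 bp in 3 mouse lists, and a gap of at least 1025 bp between neighbours. In the lists of E14.5 H3K4me2 replicate 1 and E17.5 frontal H3K27ac replicate 1, starts were offset by 1 bp on that grid. The mouse lists reach position 197068850 on chromosome 1, beyond the last gene of chromosome 1 in the GRCm38.p6 gene table at hand, and were taken as mm9. That table is of another build than the files, so no locus was assigned to a gene, and the planned gene lists and the split into promoter and distal regions were not run. All positions are written 1-based. Because the files carry no read numbers, the depth is unknown, and counting intervals were not computed.

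Loci were made by merging touching or overlapping regions of all lists of a species and mark, and kept when called in at least 2 lists. The value of a locus in a list is the length in bp covered by that list's regions. It was analysed as log2(covered bp + 200) with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, in a fit with a mean per tissue over all lists of the species and mark. E17.5 and 12 pcw were taken as the mean of their frontal and occipital tissues. Calls are at a Benjamini-Hochberg adjusted p below 0.05 within a contrast, and log2 changes are on the scale with the 200 bp added, which understates changes of short loci. Where the median change over loci exceeded 0.1, changes are also stated relative to it, while the p-values test the change itself against 0. The share of loci whose values did not overlap between the sides is set beside its mean over all divisions of the same lists into sides of the same sizes, with ties kept. Similarity of lists was the base-pair Jaccard index, tested by exact one-sided permutation of samples over tissues or ages. Marks were compared by exact two-sided permutation within pairs of a tissue and replicate, with an overlap of at least 1 bp, and species by exact two-sided permutation over 1287 splits. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these. The p-values of exact tests were adjusted within families of 4 (tissue grouping), 2 (age), 6 (marks) and 2 (species).

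The tests, their alternatives and the rule for named loci were fixed before the data were examined. Named loci are, for each contrast and mark, the 5 called loci with the largest increase and the 5 with the largest decrease whose values did not overlap between the sides, the 3 longest H3K27ac loci called in every list of a tissue, and the 3 longest called in every list of 1 mouse age and no other. A part of them is printed. The rule found no called locus in rhesus. Loci with the largest change in bp were added after their values were seen and are marked so. The alternatives were a pseudocount of 1000 bp, the replicate number as a block, loci called in at least 3 lists or in any, merging of regions up to 1000 bp apart, an equal number of the widest regions per list, covered length scaled to the list's total, presence in every list of a side and none of the other, a Jaccard index counting loci, an overlap of at least 50%, and leaving out each replicate in turn.

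The marks of a tissue and replicate were compared within pairs because the series' design text ties them to a shared input. Across loci, same-numbered deviations of the marks correlated at -0.225 to 0.222.

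The locus test was tried on the real loci with each locus's values shuffled over the lists and known changes put in. Shuffling moves differences between tissues into the spread, so that the shares below do not carry over directly to the real lists. With 200 bp added, a 4-fold longer locus had a median log2 change of 1.32 for mouse H3K27ac and 1.38 for mouse H3K4me2. For mouse H3K27ac, E17.5 against E11.5 over 85290 loci with 200 changed loci, it recovered 0% of 4-fold longer loci, 11.4% of 16-fold longer loci and 25% of loci called on 1 side, and for H3K4me2 over 63453 loci 0%, 30% and 30%. With 5000 loci called on 1 side it recovered 99.7% and 99.8%, and 19.6% and 14.9% of its calls were false, above the nominal 5%. For rhesus, 12 pcw against 8 pcw, it recovered none of the 200 changed loci in either mark, and with 5000 changed it recovered 64.0% for H3K27ac over 65601 loci and 69.5% for H3K4me2 over 73509 loci, with 5.80% and 6.51% of calls false. Calls for rhesus contrasts thus depended on how many loci changed together. The code for merging and covered length was tested against a base-by-base count.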

Results

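Developing cerebral cortex of C57BL6J mice and rhesus macaques was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) for 2 histone marks. H3K27ac, an acetylation of histone H3, is found at active promoters and enhancers. H3K4me2, a dimethylation of histone H3, is found at promoters and enhancers whether or not they are active. The mouse samples covered 4 tissues, namely cortex at embryonic day 11.5 (E11.5), when neurogenesis starts, cortex at E14.5, and frontal and occipital cortex at E17.5, late in neurogenesis. Each mouse tissue had 2 biological replicates. The rhesus samples were cortex at 8 weeks after conception (8 pcw), with 1 replicate, and frontal and occipital cortex at 12 pcw, with 2 replicates each. The series addresses changes in promoter and enhancer activity while the cortex forms. For each ChIP sample the authors deposited a list of called regions, 16 lists for mouse and 10 for rhesus, and no score or read count stood beside a region. Read depth was therefore unknown, and the number of regions and the length they cover are given in its place. Mouse positions are on mm9, and the rhesus build is not given in the sources used here.

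Mouse H3K27ac lists were shortest at E11.5 and longest in frontal cortex at E17.5. They covered 74.2 ± 15.7 Mb at E11.5, 126 ± 26.4 Mb at E14.5, 165 ± 6.36 Mb in E17.5 frontal cortex and 145 ± 22.8 Mb in E17.5 occipital cortex (mean ± SD, n = 2 each). Mouse H3K4me2 lists covered 90.5 ± 29.9 Mb, 80.3 ± 21.1 Mb, 97.4 ± 10.4 Mb and 138 ± 34.9 Mb in the same tissues, so that the longest were those of occipital cortex. The 8 mouse H3K27ac lists held 47631 to 87236 regions, and the 8 H3K4me2 lists 32366 to 76833. Regions wider than 10 kb numbered 132.5 ± 132 in the E11.5 H3K27ac lists and 1156 ± 125 in those of E17.5 frontal cortex. In rhesus, H3K27ac lists held 55282 to 72698 regions and H3K4me2 lists 30442 to 87584. The 2 rhesus H3K4me2 lists of frontal cortex at 12 pcw stood far apart, covering 61.2 Mb in replicate 1 and 184 Mb in replicate 2.

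**Figure D1:**
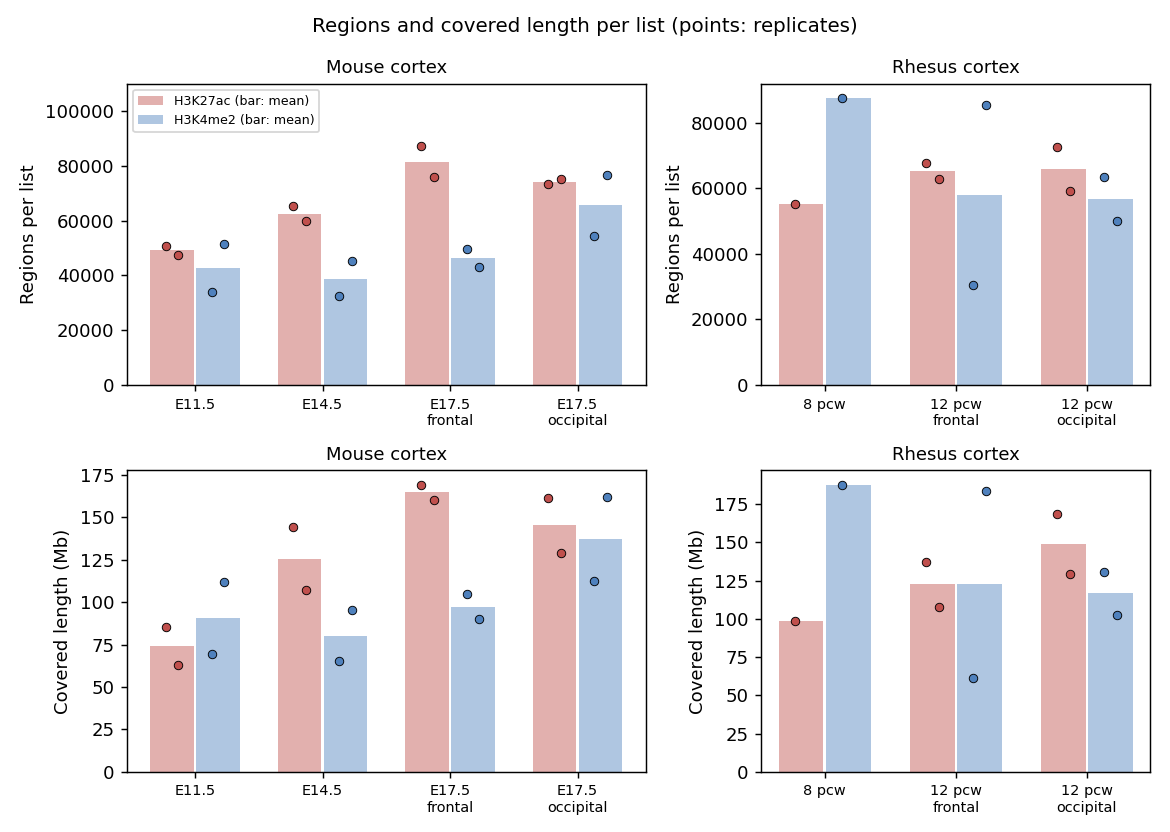
Number of regions per list (top) and covered length in Mb (bottom) for each tissue of mouse (left) and rhesus (right), with bars for the mean and points for replicates, H3K27ac in red and H3K4me2 in blue. Mean covered length of mouse H3K27ac lies between 74.2 Mb at E11.5 and 165 Mb in E17.5 frontal cortex, and the rhesus H3K4me2 points of 12 pcw frontal cortex lie at 61.2 and 184 Mb.

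H3K27ac domains are given here as loci merged over all lists of a species, and a list may cover a domain by several separate regions. The longest in mouse cortex lay on chromosome 8 from 122875276 to 123068025, a span of 192750 bp with a region in all 8 lists. The widest single region in a mouse H3K27ac list was 115300 bp, in E14.5 replicate 1. Regions covered 101488 ± 29822 bp of it at E11.5, 182300 ± 7460 bp at E14.5, 175800 ± 14849 bp in E17.5 frontal cortex and 157800 ± 30865 bp in E17.5 occipital cortex (SD, n = 2 each). A domain on chromosome 5 from 112487401 to 112601326 was covered over 18750 ± 9228 bp at E11.5, 76762.5 ± 6523 bp at E14.5, 97950 ± 19375 bp in E17.5 frontal cortex and 71150 ± 35143 bp in occipital cortex. The next, on chromosome 14 from 64986776 to 65081675, was covered over 9812.5 ± 1750 bp at E11.5, 59862.5 ± 13523 bp at E14.5, 90100 ± 3394 bp in frontal cortex and 84037.5 ± 14655 bp in occipital cortex. In rhesus the longest such domains with a region in all 5 lists lay on chromosomes 1 (6066051 to 6147025), 12 (6888976 to 6964725) and 10 (71091251 to 71164425). The domain on chromosome 1 was covered over 52750 bp at 8 pcw, 74075 ± 495 bp in frontal cortex and 64087.5 ± 15044 bp in occipital cortex at 12 pcw. That on chromosome 10 was covered over 50500 bp at 8 pcw, 63787.5 ± 7195 bp in frontal cortex and 72725 ± 636 bp in occipital cortex.

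Replicates of a mouse tissue shared more called sequence than did lists of different tissues, although not past adjustment for the 4 such tests. For H3K27ac the base-pair Jaccard index, the length shared by both lists over the length in either, was 0.520 ± 0.0316 within tissues (4 pairs) and 0.427 ± 0.104 between tissues (24 pairs). The exact one-sided permutation p over 105 assignments was 0.0476, adjusted 0.0952. For H3K4me2 the index was 0.670 ± 0.0733 within and 0.584 ± 0.0920 between tissues, with an exact p of 0.0190, adjusted 0.0762. Leaving out a single list brought the unadjusted exact p for H3K27ac to 0.0667 without E11.5 replicate 2, E17.5 frontal replicate 1 or E17.5 occipital replicate 2, to 0.0571 without E14.5 replicate 1 and to 0.114 without E14.5 replicate 2. For H3K4me2 the exact p was 0.105 without E17.5 frontal replicate 1, 0.114 without frontal replicate 2 and 0.0762 without occipital replicate 2. Among mouse H3K27ac lists, the pairs of E17.5 frontal with E17.5 occipital cortex had an index of 0.551 ± 0.0755 (4 pairs), above the 0.522 of the occipital replicates. For H3K4me2, the E11.5 replicates (0.602) lay below E11.5 with E14.5 (mean 0.622), and the E14.5 replicates (0.651) below E14.5 with frontal cortex (0.662). The frontal (0.774) and occipital replicates (0.651) lay above frontal with occipital cortex (0.633).

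In rhesus, replicates of a tissue did not stand out from lists of other tissues. The H3K27ac index was 0.439 ± 0.0146 within tissues (2 pairs) and 0.405 ± 0.0582 between (8 pairs), with an exact one-sided p of 0.133, adjusted 0.178. The H3K4me2 index was 0.446 ± 0.171 within and 0.483 ± 0.0972 between tissues, with an exact p of 0.733 before and after adjustment. With 15 assignments the smallest p was 0.0667, so that neither test could reach 0.05. The within-tissue H3K4me2 index exceeded that between tissues by 0.0523 without 12 pcw frontal replicate 1 and by 0.125 without frontal replicate 2, which turned the sign of the difference. The most similar rhesus H3K4me2 lists were frontal replicate 2 and occipital replicate 1, with an index of 0.657.

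**Figure D2:**
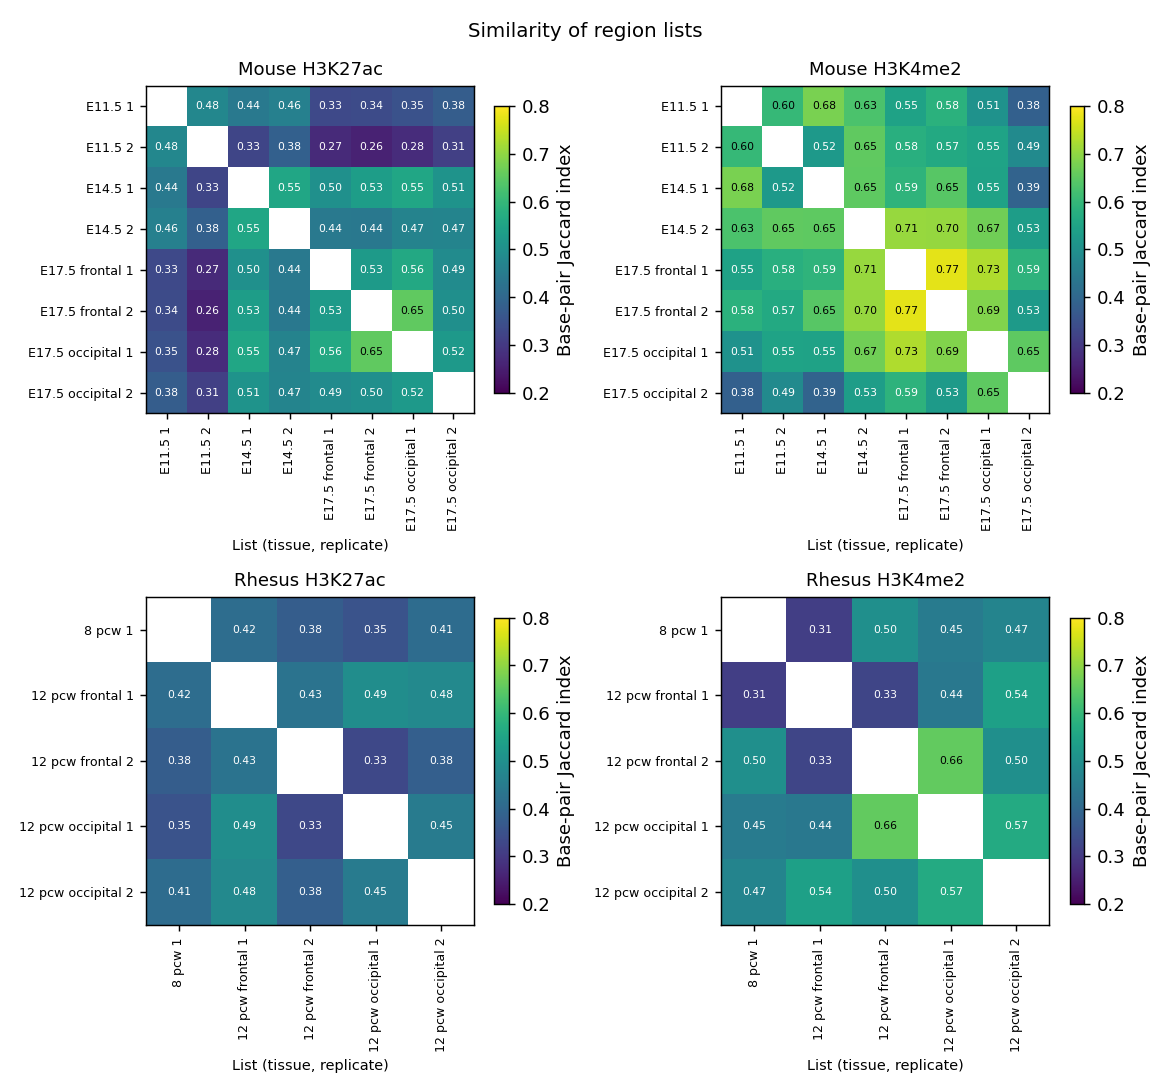
Base-pair Jaccard index (colour, and printed in each cell) for every pair of lists, by tissue and replicate number on both axes, in mouse (top) and rhesus (bottom) for H3K27ac (left) and H3K4me2 (right). Mouse H3K27ac pairs of E11.5 with E17.5 frontal cortex average 0.300, and those of E17.5 frontal with occipital cortex 0.551.

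Mouse cortices further apart in age shared less called sequence, less regularly for H3K4me2 than for H3K27ac. The H3K27ac index was 0.403 ± 0.0618 between E11.5 and E14.5, 0.300 ± 0.0405 between E11.5 and E17.5 frontal cortex, 0.329 ± 0.0436 between E11.5 and occipital cortex, 0.480 ± 0.0457 between E14.5 and E17.5 frontal cortex, and 0.500 ± 0.0402 between E14.5 and occipital cortex (4 pairs each). For H3K4me2 the corresponding values were 0.622 ± 0.0678, 0.569 ± 0.0169, 0.481 ± 0.0691, 0.662 ± 0.0560 and 0.535 ± 0.114, the last below the value of E11.5 and frontal cortex. Over 28 pairs of the 8 lists, the index fell with the age difference in days for H3K27ac (r = -0.832, rho = -0.819, exact one-sided permutation p = 0.00238 for each, the smallest that 420 assignments of ages can give). The H3K4me2 relation had r = -0.520 and rho = -0.532, with an exact p of 0.00714 for each. Adjusted over these 2 relations, the p-values for r were 0.00476 and 0.00714. The index of a pair cannot exceed the length of the shorter list over that of the longer. H3K27ac lists lengthened with age, so that list length and age are not told apart here. An equal number of the widest regions per list gave r of -0.830 for H3K27ac and -0.571 for H3K4me2, but does not make covered lengths equal. Without the 2 E11.5 lists, the farthest from the median age, r was -0.513 for H3K27ac (rho = -0.495, exact p = 0.0667 and 0.133) and -0.315 for H3K4me2 (rho = -0.247, exact p = 0.2 for each). Without them 15 assignments remain and the smallest p is 0.0667, which r for H3K27ac reached, so that these p-values do not show whether the relation rests on the E11.5 lists.

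Most of the early regions were still called late, while a larger part of the late regions had not been called early. Of 29873 H3K27ac loci called in both E11.5 lists, 81.3% were called in all 4 E17.5 lists and 4.15% in none. Of 41796 loci called in all 4 E17.5 lists, 58.1% were called in both E11.5 lists and 25.2% in neither. For H3K4me2, 81.9% of 31319 E11.5 loci were called in all E17.5 lists and 5.29% in none, and 71.2% of 36028 E17.5 loci were called in both E11.5 lists and 16.2% in neither. For H3K27ac every E17.5 list was longer than both E11.5 lists, which bears on the H3K27ac shares. For H3K4me2 this held for the occipital lists only, since the list of E11.5 replicate 2 was longer than both frontal lists. The shares also rest on unlike numbers of lists, since absence from both E11.5 lists is met more easily than absence from all 4 E17.5 lists. Between E11.5 and E14.5, with 2 lists each, 5.15% of E11.5 and 19.8% of E14.5 H3K27ac loci were absent from the other age. For H3K4me2 these shares were 7.38% and 6.12%. All 8 mouse lists shared 17.01% of 137962 H3K27ac loci and 25.9% of 91956 H3K4me2 loci, whereas 38.2% and 31.0% were called in 1 list.

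Between E11.5 and E17.5, H3K27ac appeared at loci where no region had been called, and the largest gains in bp were at loci already called at E11.5. A locus on chromosome 9 from 113532652 to 113560151 was listed at 0 bp in both E11.5 lists and covered over 22981 ± 4341 bp at E17.5 (SD, n = 4; limma adjusted p = 0.00045). So were loci on chromosome 8 from 88840102 to 88864475 (21237.5 ± 1070 bp), on chromosome 9 from 113192151 to 113218051 (20700 ± 3734 bp), on chromosome 8 from 14637602 to 14657201 (16025 ± 2691 bp) and on chromosome 13 from 70287601 to 70306625 (15750 ± 2624 bp), with limma adjusted p of at most 0.000654. Among loci called at both ages, chosen after their values were seen, the chromosome 14 domain from 64986776 to 65081675 was covered over 9812.5 ± 1750 bp at E11.5 and 87069 ± 9364 bp at E17.5 (log2 change 3.13, adjusted p = 0.00624, and 2.12 relative to the median locus, not tested). A locus on chromosome 15 from 83783327 to 83846500, chosen likewise, was covered over 6512.5 ± 725 and 59506 ± 4697 bp (3.15, adjusted p = 0.00369, and 2.15 relative to the median locus).

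H3K27ac was lost over shorter stretches. A locus on chromosome 6 from 23193551 to 23205925 went from 9862.5 ± 3553 bp at E11.5 (n = 2) to 150 ± 300 bp at E17.5 (n = 4), a log2 change of -5.11 (limma adjusted p = 0.00496), or -6.11 relative to the median locus. On chromosome 19 a locus from 44566926 to 44573850 went from 5025 ± 2546 bp to no called region (adjusted p = 0.00314), and its neighbour from 44585401 to 44594050 from 7225 ± 1909 to 237.5 ± 475 bp (adjusted p = 0.0112). A further stretch of that chromosome, 25677051 to 25691075, went from 13312.5 ± 194 to 825 ± 1029 bp (adjusted p = 0.0489). The locus on chromosome 7 from 151967101 to 151972925, covered over 4750 ± 1520 bp at E11.5, had no called region at E17.5 (adjusted p = 0.0031).

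Across the genome, 16182 of 85290 tested H3K27ac loci changed between E11.5 and E17.5, 14934 upward and 1248 downward (limma on log2 covered length, Benjamini-Hochberg adjusted p below 0.05). The median locus moved by 1.01 on the log2 scale, in step with the longer E17.5 lists. With covered length scaled to each list's total, 11380 loci were higher and 12375 lower, so that the share of higher loci was 92.3% unscaled, 47.9% scaled and 78.4% with an equal number of regions per list. Loci that rose had a median length of 3425 bp and those that fell 1350 bp. The values of the ages did not overlap at 32.8% of tested loci, where all divisions of these lists into sides of these sizes gave 9.55% on average. Shuffling each locus's values over the lists, independently of other loci, gave a median of 7 calls over 20 draws and at most 16. This breaks what a list shares across loci, so that it does not show what regrouping whole lists would give. Without E11.5 replicate 1 the count was 10496, of which 57 were lower, and without E11.5 replicate 2 it was 5928, of which 85 were lower. Of the 1248 downward calls, 769 were at loci held by the 2 E11.5 lists alone, which fall under the filter of 2 lists once either is left out. That part of the drop is built in and says little on how stable these 769 are. The drop in downward calls was larger than this part, so that the other downward calls depended on single E11.5 lists.

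H3K4me2 also spread to loci that had none at E11.5. A locus on chromosome 15 from 66655026 to 66664500 was listed at 0 bp at E11.5 and covered over 8825 ± 394 bp at E17.5 (SD, n = 4; limma adjusted p = 0.000186). Loci on chromosome 14 from 102236351 to 102245850, on chromosome 1 from 178857151 to 178867075 and on chromosome 17 from 3480802 to 3489225 reached 8325 ± 1004, 7856 ± 2012 and 7256 ± 1562 bp from 0 (adjusted p = 0.00138 for each). In the other direction, the chromosome 19 stretch from 44566876 to 44576000, which contains the first H3K27ac loss on that chromosome, went from 8637.5 ± 689 bp at E11.5 to no called region at E17.5 (adjusted p = 0.00138). Loci on chromosome 2 from 18231726 to 18240200 (7500 ± 1379 bp at E11.5) and on chromosome 9 from 75622426 to 75630200 (6700 ± 1520 bp) were likewise listed at 0 bp at E17.5 (adjusted p = 0.00141 and 0.00475). A chromosome 5 locus from 140010776 to 140029775, chosen after its values were seen, went from 16612.5 ± 3376 to 3044 ± 593 bp (adjusted p = 0.00296).

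In all, 14375 of 63453 tested H3K4me2 loci changed between E11.5 and E17.5, 12391 upward and 1984 downward (limma, adjusted p below 0.05), with a median locus shift of 0.37 on the log2 scale. The share of higher loci was 86.2%, against 74.5% (11041 higher and 3776 lower) with scaled covered length and 65.2% with an equal number of regions per list. At 27.9% of loci the values of the ages did not overlap (10.2% over all divisions of the lists). Shuffling each locus's values independently gave at most 1 call, with the same limit as for H3K27ac. Without E11.5 replicate 2 the downward count was 186 of 12824 calls. The count was 1178 without E11.5 replicate 1 (132 downward), 7098 without E17.5 occipital replicate 1 and 7354 without occipital replicate 2. The filter of 2 lists alone removes 1144 of the downward calls without either E11.5 list and 4786 of the upward calls without either occipital list. These 4786 lay at loci held by the 2 occipital lists alone, so that they were not gains in frontal cortex. Values of the ages did not overlap at 8926 of the 14375 called loci.

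Between E11.5 and E14.5 a first set of H3K27ac loci appeared. Loci on chromosome 9 from 23979401 to 23996925 and on chromosome 16 from 91888526 to 91902100 were listed at 0 bp at E11.5 and covered over 13537.5 ± 1573 and 10725 ± 1909 bp at E14.5 (SD, n = 2; limma adjusted p = 0.00188 for each). The chromosome 13 locus from 70287601 to 70306625, named above for E17.5, already held 12625 ± 3960 bp at E14.5. Downward, the chromosome 7 locus from 151967101 to 151972925 had no called region at E14.5 (adjusted p = 0.0104), nor had a locus on chromosome 11 from 102222751 to 102228075 (3900 ± 1237 bp at E11.5, adjusted p = 0.0114). Of 85290 tested loci, 5558 rose and 822 fell, with a median locus shift of 0.26 on the log2 scale. The share of higher loci was 87.1%, and 72.5% with an equal number of regions per list. The values did not overlap at 32.9% of loci (19.6% over all divisions of these 4 lists into pairs). The total of 6380 calls went to 2189 without E11.5 replicate 2, 933 without E14.5 replicate 1 and 2776 without E14.5 replicate 2, with 12, 33 and 38 downward, and without E11.5 replicate 1 25 were downward. The filter alone removes 743 downward calls without either E11.5 list and 469 upward calls without either E14.5 list.

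H3K4me2 loci were called in both directions over the same interval, in a balance that single lists turned. The chromosome 1 and 17 loci named above for their E17.5 gains were listed at 0 bp at E11.5 and held 5775 ± 2722 and 4787.5 ± 159 bp at E14.5 (SD, n = 2; limma adjusted p = 0.00342 for each). A chromosome 8 locus from 111253226 to 111257850, covered over 4037.5 ± 301 bp at E11.5, had no called region at E14.5 (adjusted p = 0.00342) or at E17.5 (adjusted p = 0.00138). The chromosome 19 stretch from 44566876 to 44576000 went from 8637.5 ± 689 to 2500 ± 636 bp, a log2 change of -1.73 (adjusted p = 0.0413, chosen after its values were seen for this interval). In total 1185 loci rose and 1317 fell among 63453. The values did not overlap at 17.8% of loci (21.0% over all divisions of these 4 lists into pairs). There were 1658 higher and 33 lower loci without E11.5 replicate 2, 2442 and 915 without E14.5 replicate 1, and 851 and 2198 without E14.5 replicate 2. The 2502 calls also depended on single lists, with 3 calls without E11.5 replicate 1 (the filter alone removes 1102 downward calls without either E11.5 list), 1266 without E17.5 frontal replicate 1 (354 higher and 912 lower), 1464 without frontal replicate 2 (531 and 933) and 1625 without occipital replicate 1 (663 and 962), and with 842 higher and 1486 lower without occipital replicate 2.

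From E14.5 to E17.5, H3K4me2 calls were mostly upward, many of them at loci called in occipital cortex alone. A chromosome 16 locus from 28879926 to 28887250 and a chromosome 7 locus from 37116076 to 37119725 were listed at 0 bp at E14.5 and covered over 4825 ± 2394 and 3431 ± 236 bp at E17.5 (SD, n = 4; limma adjusted p = 0.00653 for each). The chromosome 2 locus from 18231726 to 18240200 and the chromosome 19 stretch from 44566876 to 44576000 lost their remaining 2862.5 ± 1220 and 2500 ± 636 bp (n = 2, adjusted p = 0.00653 for each). Of 63453 loci, 8519 rose and 103 fell, with a median locus shift of 0.47 on the log2 scale. Of the upward calls, 4530 lay at loci held by the 2 occipital lists alone, so that they were not gains in frontal cortex. The share of higher loci was 98.8%, and 82.4% with an equal number of regions per list. Values did not overlap at 22.9% of loci (9.75% over all divisions of the lists), and at 3646 of the 8622 called loci. The 8622 calls went to 1 without E14.5 replicate 1, 3585 without E17.5 occipital replicate 1 and 2657 without occipital replicate 2, where the filter alone removes 4530 upward calls without either occipital list.

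For H3K27ac over that interval, the calls went both ways and depended on single lists. A locus on the X chromosome from 47963776 to 47977400 was covered over 5050 ± 3323 bp at E11.5 (n = 2), had no called region at E14.5 and was covered over 8762.5 ± 3310 bp at E17.5 (n = 4), with limma adjusted p of 0.0158 and 0.0436 for the steps. Loci on chromosome 9 from 103744226 to 103752750 and on chromosome 9 from 112921526 to 112931950 went from no called region to 7200 ± 1736 and 7200 ± 2357 bp (adjusted p = 0.0436 for each). On chromosome 8 a locus from 117963276 to 117967625 went from 4050 ± 212 bp to none (adjusted p = 0.0496). Of 85290 loci 523 rose and 445 fell, a median locus shift of 0.24, and values did not overlap at 17.2% of loci (9.88% over all divisions of the lists). The calls were not stable, since 7 of the 8 lists, left out singly, each took the count from 968 to 0, and leaving out E17.5 occipital replicate 2 took it to 5371. The filter itself removes 412 downward calls without either E14.5 list. With the loci of all lists kept, calls remained when any E17.5 list was left out, part of them at loci in 1 remaining list. None remained when an E11.5 or E14.5 list was left out. Limma also gave 0 calls with scaled covered length and 0 with a pseudocount of 1000 bp, with 15379 and 14088 loci at an unadjusted p below 0.05, and between 8421 and 13687 in the 7 comparisons that left out a list.

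**Figure D3:**
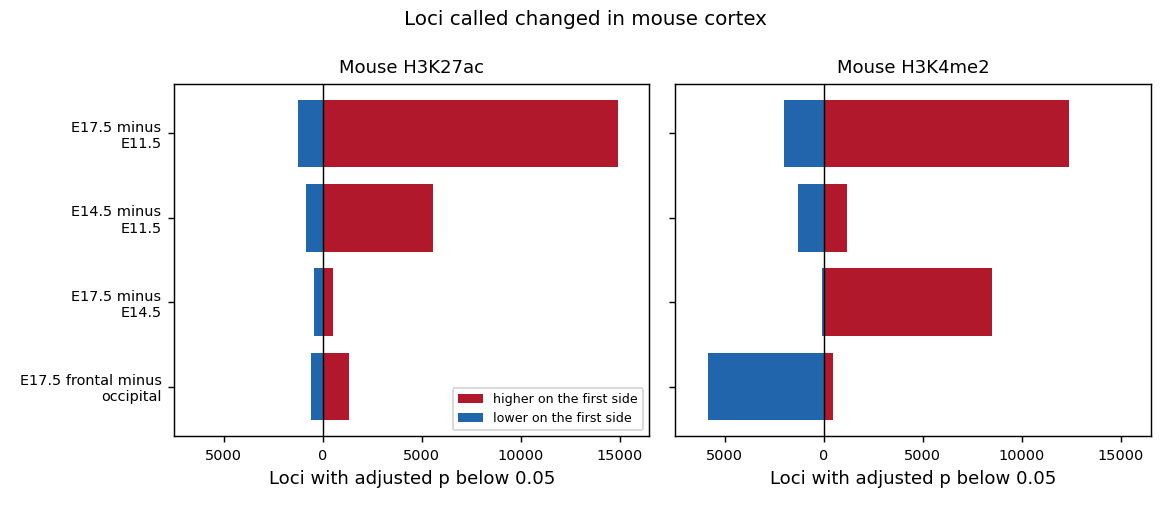
Number of loci with limma adjusted p below 0.05 (horizontal axis, lower loci to the left of 0 and higher loci to the right) in the 4 mouse contrasts (vertical axis) for H3K27ac (left) and H3K4me2 (right). H3K27ac was higher at 14934 loci and lower at 1248 from E11.5 to E17.5 (11380 and 12375 with scaled covered length, not drawn), and H3K4me2 was lower at 5856 loci and higher at 443 in E17.5 frontal than occipital cortex.

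Of the H3K4me2 loci called between the areas of the E17.5 cortex, most had more covered length in occipital cortex, whose lists were longer. A locus on chromosome 13 from 78119376 to 78126575 was covered over 6337.5 ± 1043 bp in occipital cortex and had no called region in frontal cortex (SD, n = 2 each; limma adjusted p = 0.0239). The same held for loci on chromosome 16 from 42919276 to 42925525 (5125 ± 1061 bp, adjusted p = 0.0204) and chromosome 5 from 147179751 to 147185650 (4987.5 ± 1290 bp, adjusted p = 0.0103). In frontal cortex, loci on chromosome 1 from 56991101 to 56996750 (3537.5 ± 583 bp, adjusted p = 0.000602) and on chromosome 11 from 87843926 to 87846100 (2075 ± 141 bp, adjusted p = 0.000599) were called and in occipital cortex listed at 0 bp. The broadest difference, chosen after its values were seen, was on chromosome 7 from 77468751 to 77518825, covered over 16387.5 ± 3589 bp in frontal and 48462.5 ± 1998 bp in occipital cortex, lower in frontal cortex with a log2 change of -1.57 (adjusted p = 0.00665), or -1.30 relative to the median locus.

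H3K4me2 was higher in frontal cortex at 443 of 63453 loci and lower at 5856 (limma, adjusted p below 0.05), with a median locus shift of -0.27 on the log2 scale. The share of higher loci was 7.03%, 8.60% (536 higher and 5695 lower) with scaled covered length, and 40.3% (1134 higher and 1678 lower) with an equal number of regions per list. Values did not overlap at 47.5% of loci (27.8% over all divisions into pairs), and the other divisions of these 4 lists into pairs gave 0 calls each by limma, with 969 and 2489 loci at an unadjusted p below 0.05. A pseudocount of 1000 bp gave 426 higher and 5728 lower loci, and no filter 437 and 5633. Without E17.5 occipital replicate 1, and likewise without occipital replicate 2, limma gave 0 calls (6467 and 3045 loci at an unadjusted p below 0.05), and with loci called in at least 3 lists it gave 0 as well (4977). These settings remove 5199 of the 5856 lower calls by construction, since these lay at loci held by the 2 occipital lists alone. With all loci kept, limma gave 6960 and 6797 calls without these lists, 5237 of each at loci in the remaining occipital list alone, whose spread is not seen, so that leaving out an occipital list does not settle how stable the calls are. Loci higher in frontal cortex numbered 33 without frontal replicate 1 and 78 without frontal replicate 2, where 394 of the 443 fall under the filter likewise, beside 6999 and 5039 lower loci.

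For H3K27ac the areas differed at short loci, and the calls did not hold. A locus on chromosome 5 from 31051376 to 31055926 was covered over 3637.5 ± 1114 bp in frontal cortex and had no called region in occipital cortex, and one on chromosome 16 from 43637251 to 43640625 was covered over 2625 ± 884 bp in occipital cortex and listed at 0 bp in frontal cortex (SD, n = 2 each; limma adjusted p = 0.04 and 0.0454). An X chromosome locus from 74597001 to 74601250 was covered over 2412.5 ± 795 bp in occipital cortex and at 0 bp in frontal cortex, whose replicate 1 list held few X regions. Limma called 1352 loci higher and 615 lower in frontal cortex, and values did not overlap at 19.9% of loci (27.5% over all divisions into pairs). The share of higher loci was 68.7%, and 57.2% with an equal number of regions per list. Leaving out any 1 of the 8 lists took the 1967 calls to 0 by limma, as did a pseudocount of 1000 bp, scaled covered length, and a filter at 3 lists or none, with 2175 to 9424 loci at an unadjusted p below 0.05 over these settings. The filter alone removes 1331 higher calls without either frontal list and 593 lower calls without either occipital list, but none without an E11.5 or E14.5 list. With the loci of all lists kept, calls remained when a frontal list or occipital replicate 1 was left out. Part of these lay at loci in 1 remaining list, whose spread is not seen. None remained when any other single list was left out. The other divisions of the same 4 lists into pairs gave 2221 and 5186 calls, a structure among these lists that did not follow area.

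Some H3K27ac loci were called in every list of 1 age and in no list of the other ages. There were 769 such loci at E11.5, 487 at E14.5 and 2444 at E17.5. The longest of E11.5 was the chromosome 7 locus from 151967101 to 151972925, followed by a chromosome 11 locus from 32142501 to 32148200 (3375 ± 3147 bp, n = 2). At E14.5 the longest lay on chromosome 14 from 28699451 to 28703600 (2325 ± 2581 bp) and on chromosome 6 from 53160501 to 53164400 (2437.5 ± 1149 bp). At E17.5 they lay on chromosome 13 from 57262202 to 57276350 (8312.5 ± 4877 bp, n = 4), on chromosome 10 from 98934177 to 98946850 (7206 ± 5247 bp) and on chromosome 4 from 128003627 to 128016126 (5369 ± 3675 bp). These counts are not set against chance, since the ages differ in the number and length of lists.

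In rhesus no locus passed the test in any contrast. For 12 pcw against 8 pcw, limma gave 0 calls among 65601 H3K27ac loci (6242 at an unadjusted p below 0.05) and 0 among 73509 H3K4me2 loci (1459). For frontal against occipital cortex at 12 pcw it gave 0 calls for H3K27ac (9284) and 0 for H3K4me2 (144). H3K27ac regions were called in both frontal and neither occipital list at 3389 loci, and in both occipital and neither frontal list at 3868. H3K27ac values of the areas did not overlap at 38.0% of loci and H3K4me2 values at 2.90% (29.9% and 28.1% over all divisions into pairs). Values of 12 pcw and 8 pcw did not overlap at 29.8% of H3K27ac loci (29.4% over all divisions) and at 42.8% of H3K4me2 loci (29.6%). The 8 pcw tissue had 1 replicate, assumed to vary like the others, and loci found in its list alone did not enter the test. Such loci have no region in any 12 pcw list and show no spread, so that admitting them gives calls lower at 12 pcw largely by construction. Once loci found in a single list were admitted, 9782 H3K27ac loci were called, 8428 of them lower at 12 pcw, and 27746 H3K4me2 loci, 27644 of them lower. With scaled covered length 16 H3K4me2 loci passed for age and 5 for area. Leaving out 12 pcw frontal replicate 1 gave 4790 H3K4me2 calls for area, and dividing the 4 lists into frontal replicate 1 with occipital replicate 2 against the others gave 17527, a structure among these lists that did not follow area.

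H3K27ac regions were narrower than H3K4me2 regions in mouse, and a smaller part of them carried the other mark, although neither difference passed adjustment over 6 tests. Median width was 1284 ± 215 bp for H3K27ac and 1512.5 ± 93.5 bp for H3K4me2 (SD, n = 8 pairs of a tissue and replicate; exact two-sided permutation p = 0.0469, adjusted 0.141; H3K27ac wider in 1 of 8 pairs). Of H3K27ac regions 54.9% ± 9.24 overlapped an H3K4me2 region of the same tissue and replicate, and of H3K4me2 regions 77.9% ± 11.4 overlapped an H3K27ac region (exact p = 0.0312, adjusted 0.141; H3K27ac higher in 2 of 8 pairs). Covered length was 128 ± 39.0 Mb and 101 ± 30.3 Mb (exact p = 0.172, adjusted 0.344). With an equal number of regions per list the width difference turned to 162.5 bp in favour of H3K27ac (exact p = 0.531) and the difference in overlap shrank to -1.07 percentage points (exact p = 0.211). This setting keeps the widest regions, so that lists with more regions lose more narrow ones. Mouse H3K27ac lists held 66888 regions on average and H3K4me2 lists 48354, so that the turned sign does not test the difference in width. When at least 50% of a region had to overlap, the exact p of the overlap difference was 0.0625.

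The rhesus marks showed no difference past the test. Median width was 1285 ± 215 bp for H3K27ac and 1495 ± 54.2 bp for H3K4me2 (SD, n = 5 pairs; exact p = 0.25, adjusted 0.375), covered length 128 ± 27.5 and 133 ± 54.0 Mb (exact p = 0.938, adjusted 0.938), and overlap 58.1% ± 14.6 and 63.7% ± 19.4 (exact p = 0.75, adjusted 0.9). The smallest p that 5 pairs allow is 0.0625. With an equal number of regions per list the sign of the difference in covered length turned, to 2.35 Mb more for H3K27ac. Mouse and rhesus lists had similar widths, with a mouse minus rhesus difference of -0.625 bp for H3K27ac (exact two-sided p = 1) and means of 1512.5 bp in mouse and 1495 bp in rhesus for H3K4me2 (exact p = 0.731, adjusted 1 for both; 8 mouse and 5 rhesus lists). An equal number of regions per list turned both signs, to mouse minus rhesus differences of 26.25 bp and -359.375 bp. Since the widest regions are kept, these values too depend on list size and do not test width.

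Regions on the X chromosome made up 1.02% of the H3K27ac regions of E17.5 frontal replicate 1 and between 2.65% and 3.48% in the other 7 mouse H3K27ac lists. The 8 mouse H3K4me2 lists had 2.44% to 3.38%. Y chromosome regions numbered 1 in that frontal list, 0 in the H3K4me2 list of E14.5 replicate 1 and 10 to 81 in the other mouse lists. In rhesus, the H3K27ac lists of 12 pcw frontal replicate 2 and occipital replicate 1 ended early on 10 chromosomes. On chromosome 14 their last regions ended at 107234850 and 107234900, at least 25.8 Mb before the last region of another list, and on chromosome 13 at 114929550 and 114929475, at least 23.1 Mb before it. Past such positions these lists held 3 and 4 regions, and the other 3 rhesus H3K27ac lists 3511 to 4362.

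**Figure D4:**
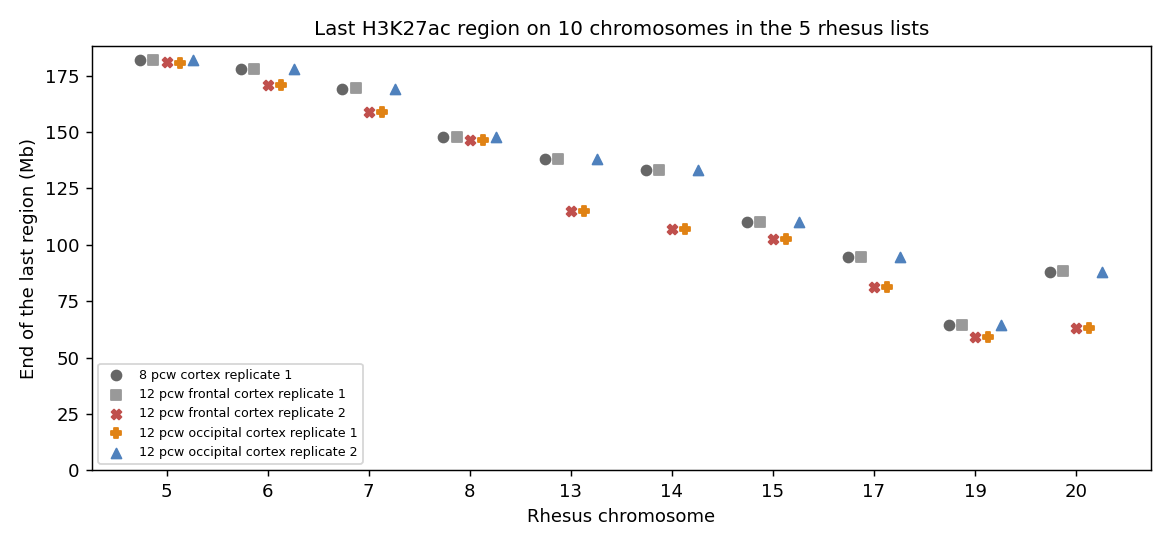
End position in Mb (vertical axis) of the last H3K27ac region on 10 rhesus chromosomes (horizontal axis) in each of the 5 lists, with a symbol for each list. Those of 12 pcw frontal replicate 2 and occipital replicate 1 lie together below the others, by at least 25.8 Mb on chromosome 14 and at least 1.19 Mb on chromosome 5.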

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

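All tests in this part were chosen after the results they bear on were seen. The share of regions on the X chromosome stood apart in 1 list, at 1.02% in E17.5 frontal H3K27ac replicate 1 against 2.65% to 3.48% in the other 7 mouse H3K27ac lists. It was the 1 outlying value in 16 sets of lists examined, and chance flags about 1 in 20 groups. Loci called in the other 7 lists were missing here for 0.786% of autosomal loci and 12.1% of X loci, which argues against a stricter list throughout the genome. A different X dosage of the embryos stays open, as the H3K4me2 list of the same tissue and replicate had 2.72% X regions, neither the lowest share of its mark nor above the median. A separate run of the region calling is a candidate source, since the other list with starts offset by 1 bp had the lowest X share of the mouse H3K4me2 lists, 2.44%, and these lists also held the fewest Y regions (1 and 0), but with a single other list this may be coincidence.

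The rhesus H3K27ac lists of 12 pcw frontal replicate 2 and occipital replicate 1 held 3 and 4 regions beyond the earlier of their 2 last region ends on 10 chromosomes. Their last regions ended at a median distance of 6.51 kb from each other on those chromosomes, as a fixed limit per chromosome in making these lists would give. A loss of H3K27ac in these tissues is argued against, because the other replicate of each tissue had at least 5.93% of its regions there. Chromosome sizes of another genome may be the source of such a limit, which was not tested.

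In E17.5 cortex, H3K4me2 was lower in frontal than occipital cortex at 5856 loci and higher at 443. With an equal number of regions per list, 40.3% of calls were higher in frontal cortex, against 7.03% in the full lists and 8.60% (536 higher and 5695 lower) with covered length scaled to the list's total. Scaling left the imbalance almost as it was but cannot fill loci that the shorter lists lack, so that longer occipital lists may or may not be a part of it. A single occipital library as the source stays open. In both occipital lists and neither frontal list 8127 loci were called, against at most 2326 in 1 occipital and 1 frontal list alone. Both occipital lists were longer than the frontal lists, which may give such a count whatever the source. By the Jaccard index, occipital replicate 1 was closer to frontal replicates 1 and 2 (0.729 and 0.687) than to occipital replicate 2 (0.651). Too few lists carry the contrast for the length of the lists and the area to be told apart, and a difference between the areas stays open.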

How the results depend on the processing

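The restriction to autosomes, the removal of the rhesus chromosome ends, the crossed replicate block and leaving out a replicate with all loci kept were chosen after the data were seen. Of 335 alternative values for 26 results, 212 stayed within the limits (165 counts of loci by a total within 1.5 times, the others by direction and side of the threshold), 10 kept the direction and lost the threshold, 107 counts moved by more and 6 differences changed sign. Of the 165 counts, 7 turned the larger direction: H3K27ac for E17.5 against E11.5 when scaled, and H3K4me2 for E14.5 against E11.5 when scaled, with no filter, and without E11.5 replicate 2 or E14.5 replicate 1 (with and without all loci kept). In 24 of the 165, the number of higher or of lower loci by itself moved past 1.5 times, although the total did not. The 8 alternatives for the age relation were all among the 212. Read depth is unknown, so list length stands in for it, and the cause of the changes below was not tested except where fewer lists or loci entered by construction.

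Leaving out 1 replicate gave, for mouse H3K27ac, 5928 to 16709 changed loci for E17.5 against E11.5, 933 to 6564 for E14.5 against E11.5, 0 to 5371 for E17.5 against E14.5 and 0 to 0 for frontal against occipital cortex. For mouse H3K4me2 it gave 1178 to 15763, 3 to 3357, 1 to 10652 and 0 to 7158. In rhesus it gave 0 throughout (limma), except 0 to 4790 for H3K4me2 between areas, the 4790 without 12 pcw frontal replicate 1. With the loci of all lists kept, so that none fell under the filter, it gave 6558 to 17811, 1872 to 7089, 0 to 6425 and 0 to 3130 for mouse H3K27ac, 9555 to 15557, 1470 to 3565, 1 to 10302 and 5547 to 7416 for mouse H3K4me2, and up to 4143 (age) and 2830 (areas) for rhesus H3K27ac and 8005 and 5285 for rhesus H3K4me2. Loci in 1 remaining list, whose spread is not seen, made 97.1% (age) and 99.7% (areas) of these calls for rhesus H3K27ac and 94.6% (age) for rhesus H3K4me2. There this setting makes calls of its own. For rhesus H3K4me2 between areas such loci made 3.51%, so that most of those calls did not come about in this way. Tissue grouping ranged from 0.0665 to 0.109 for mouse H3K27ac, from 0.0597 to 0.115 for mouse H3K4me2, from 0.0153 to 0.0789 for rhesus H3K27ac and from -0.146 to 0.125 for rhesus H3K4me2, where the sign changed without frontal replicate 1 (0.0523) or frontal replicate 2 (0.125).

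A pseudocount of 1000 bp left 2971 (H3K27ac, E14.5 against E11.5), 0 (E17.5 against E14.5), 0 (frontal against occipital) and 1078 loci (H3K4me2, E14.5 against E11.5). Loci called in at least 3 lists gave 6 and 0 for the latter 2 H3K27ac contrasts, and for H3K4me2 6768, 600, 3118 and 0 in the order above. No filter gave 72 and 0 for H3K27ac, 8449 (E17.5 against E11.5) and 3011 (E17.5 against E14.5) for H3K4me2, and, for rhesus age, 9782 H3K27ac and 27746 H3K4me2 loci. An equal number of regions gave 2857 and 748 for H3K27ac and 9187, 3736 and 2812 for H3K4me2 (E17.5 against E11.5, E17.5 against E14.5, areas). Scaled covered length gave 0 and 0 for H3K27ac, and 16 and 5 for rhesus H3K4me2. Presence in every list of a side and none of the other gave 9798, 3816 and 4055 for H3K27ac, 7478, 4102 and 3126 for H3K4me2, and 3938, 7257, 376 and 579 for rhesus. Beside the limma counts of 0, unadjusted p was below 0.05 at 8421 to 15379 H3K27ac loci for E17.5 against E14.5, at 2175 to 9424 between mouse areas, and at 3045 to 6467 H3K4me2 loci between mouse areas.

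With the replicate number as a block, H3K27ac counts were 0 for E17.5 against E14.5 and 0 between areas, and no other total moved past the limits (13053 for E17.5 against E11.5), although H3K4me2 loci higher at E14.5 than E11.5 went from 1185 to 656. Whether same-numbered replicates of different tissues share animals is not given in the sample labels. Same-numbered deviations correlated at -0.393 to 0.305 between tissues of a species and mark, which does not decide it. If animals are shared, the frontal and occipital lists of an age are not fully independent. Pairing replicate 1 of an area with replicate 2 of the other, the crossed replicate block, gave 0 for mouse H3K27ac and 0 for rhesus H3K4me2 (4297 and 376 at an unadjusted p below 0.05). With no replicate block, the mouse mark differences had exact p of 0.0188 for width and 0.00171 for overlap.

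With an equal number of regions per list, H3K27ac regions were wider than H3K4me2 regions by 162.5 bp in mouse, the overlap difference was -1.07 points, rhesus H3K27ac covered 2.35 Mb more, and the mouse to rhesus width differences were 26.25 bp (H3K27ac) and -359.375 bp (H3K4me2). Keeping the widest regions raises widths more in lists with more regions, so that these width values do not test width. With an overlap of at least 50% the mouse difference was -22.7 points (exact p = 0.0625).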

Other observations

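All tests in this part were chosen after the results they bear on were seen. At loci called as changed between E11.5 and E17.5 in both marks, most calls had the same direction, which did not hold in every contrast. Of loci called in both, 4367 rose in both marks, 133 fell in both, 47 rose in H3K27ac and fell in H3K4me2, and 8 did the reverse. The share in the same direction was 98.8%, but the excess of upward calls in each mark would alone give 93.2%, so that the share does not decide whether the marks changed together. The odds ratio was 1545 across loci, which are not independent replicates. Of H3K27ac loci overlapping a tested H3K4me2 locus, H3K4me2 had risen at 39.8% of the 10968 that rose, at 14.1% of the 40424 not called and at 1.74% of the 461 that fell. It had fallen at 0.429%, 2.88% and 28.9% of these loci. An excess of upward calls in each mark would not alone give such differences between the classes. Between E11.5 and E14.5, 452 loci were higher in both marks, 45 lower in both, 12 higher in H3K27ac and lower in H3K4me2, and 0 the reverse. From E14.5 to E17.5, 148 were higher in both, but of the loci lower in H3K27ac 12 were higher and 3 lower in H3K4me2. Between frontal and occipital cortex, of the loci higher in H3K27ac 9 were higher and 27 lower in H3K4me2, and of those lower in H3K27ac 60 were lower and 0 higher. The shared inputs of a replicate stay open as a source of a shared direction. Longer E17.5 lists may add to the shared rises but would not give the 133 loci that fell in both marks. For H3K4me2 the E17.5 frontal lists were not longer than that of E11.5 replicate 2.

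A hypothesis was that loci gaining H3K27ac by E17.5 already carried H3K4me2 at E11.5. Among loci without H3K27ac at E11.5, 7.68% of 9882 gained loci and 5.12% of 27820 other loci had an H3K4me2 region in both E11.5 lists. Over 10 classes of locus length the Mantel-Haenszel odds ratio was 1.55, with gained loci higher in 7 of the 10 classes and lower among the shortest loci, so that the hypothesis was left undecided. Most gained loci thus lacked an H3K4me2 region in at least part of the E11.5 lists. How many had no H3K4me2 region in any E11.5 list was not counted.

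A further hypothesis was that gains cluster along chromosomes. In 2.62% of 2483 windows of 1 Mb (65 windows), gained H3K27ac loci exceeded their genome share of 17.51% by Fisher's exact test with adjustment over windows, against 0 windows for lost loci, of which there were fewer. The leading windows were chromosome 2 from 7000001 to 8000000, with 42 of 75 loci gained, chromosome 9 from 113000001 to 114000000, with 35 of 59, and chromosome 9 from 47000001 to 48000000, with 45 of 100. The share of windows was too low to show a general clustering and too high to exclude it, and a broad domain split into several loci may count more than once.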
